A study of Danio rerio with 12 samples.

How the data were processed

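Whole wild-type zebrafish embryos were sequenced in 12 libraries, 4 from each of 3 groups, and the groups were taken from the sample titles. The titles and library names divide the libraries into DMSO, GW9662 and rosiglitazone, but another field of the labels names a different compound (TBBPA) for the GW9662 libraries and DMSO for the rosiglitazone libraries. The titles were used because the library names and the description of the design go with them. A batch tag gives each library its own hour, from 24 to 35 hours post-fertilisation, rising through the groups in order, and could not be a term of a model. What the tag records is not clear, and a reading of it as the age of the embryos is tested in the closing part. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 and assigned to genes with featureCounts 1.5.0-p3. The genome build is not given in the sources used here, and the notes describe both strand-specific and unstranded library preparation, so genes that overlap on opposite strands are uncertain. So are near-identical gene copies.

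The deposited values are FPKM, which the authors computed per gene and library. FPKM times gene length gave whole multiples of a single step in each library for 100% of values (tolerance 0.001), so fragments per gene could be recovered. These sum to between 12.8 and 22.7 M per library. The library size that the values imply lay between 0.957 and 1.04 of that sum, so the authors had applied a scaling specific to each library. Of 31901 genes listed, 5756 had no fragment in any library. Gene symbols turned into dates by a spreadsheet numbered 19, of which 17 were restored from a reference of gene names. Of the genes listed, 3370 repeated a symbol already given to another gene ID, so tests were run by ID.

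Tests were run on log2(FPKM + 0.5) for the 14433 genes with at least 1 FPKM in at least 4 of the 12 libraries, of which 13933 were protein coding. One limma model with a trend in the prior variance was fitted to all 12 libraries, with 3 contrasts, and p-values were adjusted by the Benjamini-Hochberg method within each contrast at 0.05. All tests were two-sided unless stated. The 30 gene lists held 738 symbols, of which 721 were matched, and were tested with camera at a preset correlation of 0.01, adjusted over 90 tests, for lists with at least 5 measured genes. Where the estimated correlation is named, camera estimated it from the residuals of each list. Error is the SD of the 4 libraries for FPKM and the SE of the model for log2 changes.

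The lists, filters, thresholds, comparisons, most of the alternatives and the rule for naming genes were chosen before the data were examined. The rule took, in each comparison, genes with an adjusted p under 0.05, a mean of at least 2 FPKM in a group, 4 libraries all on one side of the 4 of the other group and a proper symbol. Of these it named the 8 largest rises and the 8 largest falls against DMSO, and 5 of each between the compounds. It added up to 4 members of each list with the smallest adjusted p in either DMSO comparison, and pparg, pparaa, pparab, pparda and ppardb. Every other gene named was chosen after its values were seen.

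Data were simulated with a spread modelled on the DMSO libraries and with changes of 1.25, 1.5, 2 and 4-fold. These were recovered for 30.6, 50, 85.7 and 95.9% of genes in the GW9662 comparison and 31.1, 72, 78.7 and 100% in the rosiglitazone comparison. Changes under 1.5-fold were therefore often missed. False calls were 7.19% (10 of 139) and 2.16% (3 of 139), and none of 30 unchanged lists was called. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called without a change. Whether equal replicate numbers pair libraries was checked from residual correlations, which ran from -0.0502 to 0.228 for GW9662 with DMSO, -0.0103 to 0.0751 for rosiglitazone with DMSO and 0.0377 to 0.199 between the compounds. Equal numbers matched best for 2 of 4 replicates of GW9662 with DMSO (replicates 3 and 4, at 0.228 and 0.216). They did so for 1 replicate of rosiglitazone with DMSO and 1 between the compounds. This gave no clear basis for pairing, and a replicate block was tried as an alternative. Fragment counts of replicates varied 3.06 to 14.6 times more than counting alone would give.

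The alternatives were pseudocounts, filters, scalings, variance models, list tests, a replicate block, divided controls and leaving out each library, and their effect is given in the closing part. R 4.3.3 with limma 3.58.1 and data.table version 1.17.8 did the tests, and Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 drew the plots. The imaging and staining named in the description of the study were not analysed here.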

Results

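RNA was sequenced from whole wild-type zebrafish embryos held in solution from 6 to 24 hours post-fertilisation. There were 12 libraries in 3 groups of 4: vehicle (0.1% DMSO), 75 µM GW9662 and 25 µM rosiglitazone. GW9662 is an irreversible inhibitor of the nuclear receptor PPARγ, a regulator of fat storage genes, and rosiglitazone is an agonist of the same receptor. The doses of the compounds differed, so a larger response to one of them is not a larger potency. The fragments assigned to genes averaged 16.1 ± 2.63 M per library in the DMSO libraries (SD, n = 4, from 12.8 to 19.0), 18.1 ± 3.10 M in the GW9662 libraries (from 16.2 to 22.7) and 18.7 ± 3.14 M in the rosiglitazone libraries (from 15.2 to 21.5). Comparing each compound with DMSO asked which transcripts of the embryo change when the receptor is inhibited or activated early in development. Comparing GW9662 with rosiglitazone asked which changes separate the inhibitor from the agonist. Folds below are ratios on the FPKM + 0.5 scale, which understates changes of genes with low values.

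The 12 libraries separated by group. Within a group the median correlation of log2 values was 0.987, against 0.960 between DMSO and GW9662 libraries, 0.979 between DMSO and rosiglitazone libraries and 0.968 between the compounds. The main axis of variation held 44.5% of the variance and placed GW9662 at 29.8 to 34.4, far from DMSO at -23.1 to -21.8, with rosiglitazone between them at -11.9 to -9.08. The next axis held 13.9% and parted DMSO, at 11.7 to 15.8, from rosiglitazone, at -19.8 to -15.0. The 4 libraries of a compound lay wholly above or wholly below the 4 DMSO libraries for 36.96% of tested genes with GW9662 and 20.51% with rosiglitazone, where chance gives 2.86%. The make-up of the RNA was similar but not identical: mitochondrially encoded genes took 3.32 ± 0.136% of fragments in DMSO, 2.93 ± 0.125% in GW9662 and 3.26 ± 0.0570% in rosiglitazone (SD, n = 4). Nuclear ribosomal RNA took 0.00291 ± 0.000497%, 0.00547 ± 0.000417% and 0.00298 ± 0.000669%, a trace in each group. The p-values below measure only the spread between these libraries, since nothing in the labels says that replicates came from separate clutches.

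**Figure D1:**
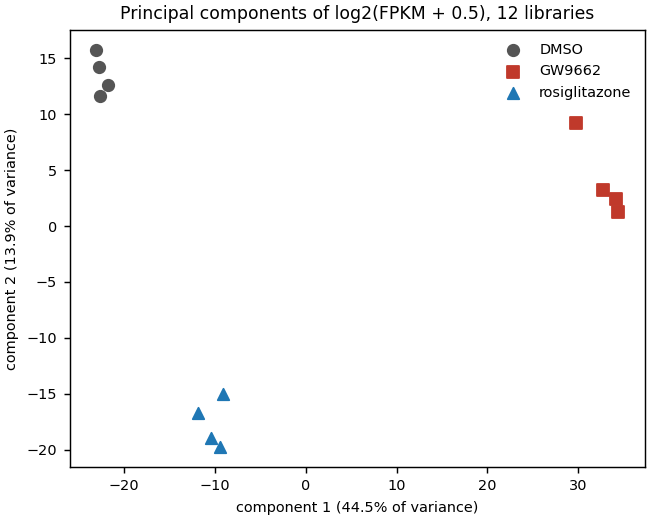
Position of the 12 libraries on the first and second principal components of log2(FPKM + 0.5), which held 44.5% and 13.9% of the variance; each point is a library, coloured by group. GW9662 lay at 29.8 to 34.4 on the horizontal axis, and DMSO and rosiglitazone parted on the vertical axis.

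Embryos held in GW9662 carried a strong stress signature and had lost much of their muscle and lens transcript. The heat shock gene hsp70.3 rose 12.9-fold, from 6.87 ± 0.511 to 94.9 ± 10.9 FPKM (SD, n = 4), and the glutathione transferase gstp1 rose 7.95-fold, from 163 ± 5.65 to 1300 ± 58.1 FPKM. The muscle calcium buffer pvalb1 was 12.6-fold lower, at 42.4 ± 8.58 against 534 ± 36.9 FPKM, and the lens crystallin cryba1b was 9.23-fold lower, at 3.36 ± 0.742 against 34.7 ± 1.47 FPKM. Of 14433 genes tested, 5196 passed an adjusted p of 0.05, 2735 higher and 2461 lower, and 568 of them changed at least 2-fold. The balance of directions depended on the scaling, with 2529 higher and 3001 lower under quantile normalization. Of 30 gene lists, 14 passed, 7 higher and 7 lower. None of the 14 held with an estimated correlation between genes, for which the adjusted p is given beside each list. Where a list has a single pair of counts below, the count over all genes tested and the count adjusted over the list alone were the same.

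The chaperone, redox and damage genes rose together. Of 18 heat shock genes, 14 were higher and 1 lower over all genes tested, and 14 and 2 adjusted over the list alone (median log2 change 0.64, camera adjusted p = 5.28e-10; adjusted p = 0.0576 with an estimated correlation). The cytosolic chaperone hsp90aa1.2 went from 29.7 ± 0.618 to 277 ± 3.30 FPKM, and the co-chaperone dnajb1b rose by a log2 of 1.90 ± 0.0491 (SE). The hsp70.1 and hsp70.2 genes rose by 3.42 and 3.37, but these copies are nearly identical to hsp70.3 and their reads may not be told apart. The lower member was the intraflagellar transport gene hspb11, at -0.31. Members named only because few of a list passed or went that way, and any other gene outside the rule for naming genes, were chosen after their values were seen. Of 25 oxidative stress and glutathione genes, 14 were higher and 3 lower, by either count (median 0.57, adjusted p = 8.96e-06; adjusted p = 0.0686 with an estimated correlation). The autophagy receptor sqstm1 rose 6.77-fold to 50.4 ± 4.88 FPKM, the glutathione reductase gsr by a log2 of 2.29 ± 0.0898, and the peroxiredoxin prdx1 by 1.08 ± 0.0576. Not every antioxidant gene followed: the superoxide dismutases sod2 and sod1 and the catalase gene cat fell by 0.46, 0.18 and 0.41.

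Of 23 genes of the unfolded protein and amino acid stress responses, 13 were higher and 1 lower over all genes tested, and 15 and 1 adjusted over the list alone (median 0.23, adjusted p = 9.33e-05; adjusted p = 0.0686 with an estimated correlation). The transcription factor ddit3, which acts late in this response, went from 5.68 ± 0.621 to 27.1 ± 2.61 FPKM. The related factors atf3 and cebpg rose by a log2 of 1.92 and 0.53, and the growth brake sesn2 by 1.22. The disulfide isomerase pdia4 fell by 0.22. Of 19 targets of the tumour suppressor p53, 13 were higher and 1 lower (median 0.63, adjusted p = 7.91e-05; adjusted p = 0.0576 with an estimated correlation). They included the cell cycle inhibitor cdkn1a, 2.63-fold higher at 15.9 ± 0.769 FPKM, the death gene bbc3, higher by a log2 of 1.53, and the damage genes gadd45aa and gadd45ba, by 1.53 and 1.03. Only tp53inp1 was lower, at -0.20. Of 17 hypoxia genes, 9 were higher and 1, ndrg1a at -0.24, lower (median 0.24, adjusted p = 0.0109; adjusted p = 0.0686 with an estimated correlation). The carbonic anhydrase ca9, the growth factor binding protein igfbp1a and the glycolytic switch pfkfb4b rose by 1.60, 1.60 and 1.16.

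Muscle fibre genes gave the smallest p of the 30 lists. Of 36 skeletal muscle genes, 30 were lower and 2 higher, by either count (median -1.21, adjusted p = 3.09e-19; adjusted p = 0.0925 with an estimated correlation). The fast troponin tnnt3b fell 6.01-fold, from 141 ± 5.81 to 23.1 ± 1.68 FPKM, the skeletal actin acta1b by a log2 of 1.89 and the myosin myhz1.2 by 2.71, a value shared among near-identical copies. Of the regulators that act before fibres form, myog and myf5 went the other way, higher by 1.02 and 0.68. These were the 2 higher members, so the early regulator myod1 was not called higher. Of 23 eye and lens genes, 16 were lower and 3 higher (median -1.39, adjusted p = 5.28e-10; adjusted p = 0.0576 with an estimated correlation). The lens water channel mipb fell 7.98-fold to 0.110 ± 0.0381 FPKM, and the crystallin cryba2a by a log2 of 2.99. Of the 8 largest falls picked from all genes, 7 were crystallin genes, led by crygmx at -3.80 ± 0.262, though crygmxl2, crygm2d8 and crygm2d13 rested on 5, 6 and 7 fragments over the 4 GW9662 libraries. The eye genes rx3, aldh1a3 and six3b were higher, by 0.44, 0.41 and 0.21.

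Neural, pigment and proliferation genes fell more mildly. Of 32 neural progenitor and neuron genes, 19 were lower and 1, the motor neuron gene isl2a at 0.47, higher (median -0.23, adjusted p = 3.82e-05; adjusted p = 0.154 with an estimated correlation). The radial glia gene fabp7a fell by 1.18, the Notch effectors her4.1 and her4.2 by 1.17 and 1.11, and the progenitor factor sox3 by 0.48. Of 22 neural crest and pigment genes, 12 were lower and 5 higher (median -0.59, adjusted p = 0.013; adjusted p = 0.288 with an estimated correlation). The pigment enzymes tyrp1b, gch2, tyrp1a and dct fell by 1.52, 1.02, 1.01 and 0.83, whereas crestin, snai1b, foxd3, trpm1b and snai2, most of them early crest genes, rose by 0.74, 0.60, 0.47, 0.26 and 0.23. Of 30 cell cycle genes, 13 were lower over all genes tested and 14 adjusted over the list alone, and 1, kif11 at 0.19, was higher (median -0.17, adjusted p = 0.00115; adjusted p = 0.509 with an estimated correlation). The nucleotide synthesis genes tyms and rrm1 fell by 0.50 and 0.29.

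Genes of the unsegmented tail mesoderm were higher. Of 24 tailbud and segmentation genes, 15 were higher and 3 lower over all genes tested, and 17 and 3 adjusted over the list alone (median 0.49, adjusted p = 9.63e-04; adjusted p = 0.0686 with an estimated correlation). The presomitic factors tbx6 and msgn1 rose by a log2 of 0.99 and 0.88 and the clock gene her1 by 0.69, while her12, hes6 and dlc fell by 0.94, 0.44 and 0.34. Of 26 extracellular matrix genes, 12 were higher and 3 lower over all genes tested, and 13 and 3 adjusted over the list alone (median 0.17, adjusted p = 0.0139; adjusted p = 0.328 with an estimated correlation). Fibronectin fn1b, versican vcana and laminin lamb1a rose by 1.64, 0.86 and 0.67, and the collagens col6a1, col6a2 and col1a1b fell by 0.67, 0.55 and 0.29. With a stricter filter on low genes, the calls of the tailbud, hypoxia and pigment lists ended, at adjusted p of 0.116, 0.146 and 0.161.

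Of 24 glycolysis genes, 12 were lower and 4 higher over all genes tested, and 13 and 4 adjusted over the list alone (median -0.34, adjusted p = 0.00373; adjusted p = 0.528 with an estimated correlation). The muscle forms pfkma and eno3 fell by 1.40 and 1.04, and ldhba, gpia, pgam1a and gapdhs rose by 0.63, 0.44, 0.20 and 0.17. Of 13 mitochondrially encoded genes, 8 were lower over all genes tested and 10 adjusted over the list alone, with none higher (median -0.27, adjusted p = 0.00184; adjusted p = 0.509 with an estimated correlation), as for mt-nd2 at -0.58 and mt-atp6 at -0.47. Of 25 fatty acid oxidation genes, 8 were lower and 2 higher, and the list did not pass (adjusted p = 0.12), except with no filter on low genes (0.0451).

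The receptor itself did not change detectably in transcript. The pparg gene stood at 1.52 ± 0.552 FPKM in DMSO and 1.27 ± 0.209 in GW9662 (log2 -0.16 ± 0.165 (SE), adjusted p = 0.488). Its relative pparaa fell by 0.76 ± 0.127, pparda and ppardb did not pass, at -0.43 and 0.10, and pparab was too low to be tested. The 14 receptors and cofactors, of which ppargc1b and rxraa were higher, by 0.48 and 0.52, and pparaa, rxrgb and rxrga (listed as CU855759.1) lower, the latter by -0.43 and -0.35, did not move as a list (median 0.07, mean -0.04, adjusted p = 0.788). Of 22 PPARγ target and lipid storage genes, 9 were higher and 6 lower over all genes tested, and 9 and 7 adjusted over the list alone, with no common direction (median 0.02, adjusted p = 0.573). The gluconeogenic gene pck1 rose 4.92-fold to 23.6 ± 1.66 FPKM and cebpb by a log2 of 1.27, whereas the glycerol enzyme gpd1b fell by 0.75.

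Among single genes, the GTPase gene arf4b went from 0.283 ± 0.0751 to 19.4 ± 5.28 FPKM, a rise of 24.9-fold that rests on 20 fragments over the 4 DMSO libraries. The peptidase anpepb, the itaconate enzyme gene irg1l, the dehydrogenase-like dhrs13l1 and the nuclear redox gene pir rose by a log2 of 4.11, 3.88, 3.61 and 3.21. The epidermal keratin krtt1c19e and the apolipoprotein apoea fell by 2.56 and 2.87, and the fin fold genes and1, and2 and and3 by 1.59, 2.47 and 2.27. Of 22 epidermis genes, however, 7 were higher and 9 lower (adjusted p = 0.456). The lists for yolk lipoprotein (9 of 23 higher, 10 lower; adjusted p = 0.573), heart (5 of 16 higher, 3 lower; 0.506) and notochord genes (4 of 17 each way; 0.985) did not pass. Erythroid genes (7 of 21 higher and 3 lower over all genes tested, 8 and 3 adjusted over the list alone; adjusted p = 0.204) and endothelial genes (5 of 16 higher and 1 lower, 6 and 1 adjusted over the list alone; 0.242) did not pass either. Hatching gland genes, 5 of 8 higher and 1 lower, came close (0.0573), and passed without DMSO replicate 1 (0.0363), GW9662 replicate 1 (0.0361) or rosiglitazone replicate 1 (0.0386). Among 6 targets of the aryl hydrocarbon receptor, the xenobiotic enzymes cyp1a and cyp1c1 rose by 0.94 and 1.35, without a call of the list (0.564). Of 11 fatty acid synthesis genes, 4 were lower and 1, mid1ip1l at 0.42, higher (0.278), the desaturase fads2 and the elongases elovl6 and elovl2 falling by 1.15, 1.04 and 0.80. Cholesterol synthesis genes also showed no common change, with 5 of 19 higher and 3 lower over all genes tested, and 6 and 3 adjusted over the list alone (median -0.07, mean 0.05; adjusted p = 0.639). Among the sterol genes, fdps and sqlea rose by 0.74 and 0.57, and acat2, hsd17b7 and mvda fell by 0.62, 0.48 and 0.29.

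Key genes are identified by Ensembl ID and by chromosome, start and end as listed with the values, without a named genome build. They are hsp70.3 (ENSDARG00000021924, chromosome 3, 26123736 to 26127091), hsp90aa1.2 (ENSDARG00000024746, chromosome 20, 53967350 to 53981626), gstp1 (ENSDARG00000104068, chromosome 14, 3507326 to 3514055), pvalb1 (ENSDARG00000037789, chromosome 3, 61193890 to 61205711) and cryba1b (ENSDARG00000053875, chromosome 21, 39185461 to 39195314). The genes followed in the rosiglitazone comparison are msgn1 (ENSDARG00000070546, chromosome 4, 306036 to 308006), cyp51 (ENSDARG00000042641, chromosome 19, 598657 to 617246), sqlea (ENSDARG00000079946, chromosome 16, 43401005 to 43413293), fads2 (ENSDARG00000019532, chromosome 25, 4133488 to 4148719) and pparg (ENSDARG00000031848, chromosome 11, 609516 to 669558).

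**Figure D2:**
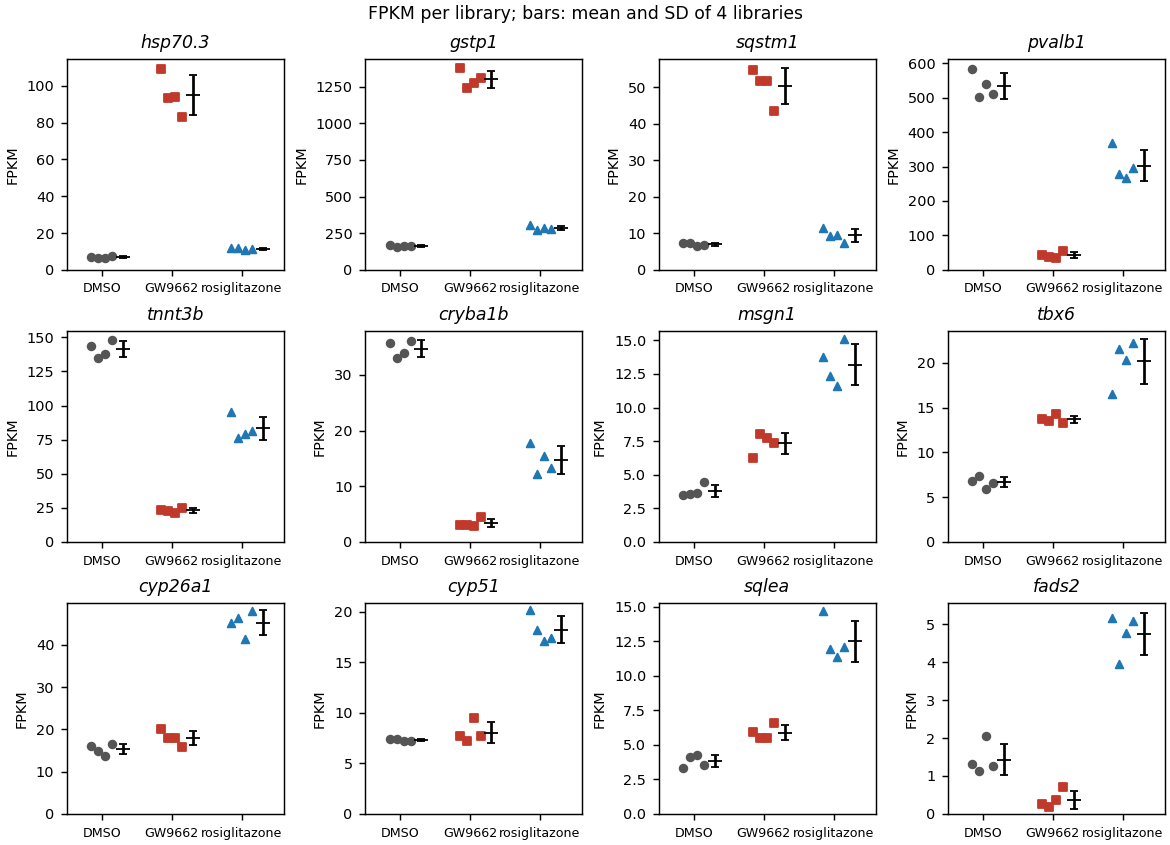
FPKM of 12 genes in each library, a point per library, with the mean and SD of the 4 libraries of each group. For hsp70.3 and gstp1 the 4 GW9662 libraries lie above all others, and for msgn1, cyp51 and fads2 the 4 rosiglitazone libraries do.

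Rosiglitazone gave a smaller response, in which the sterol pathway was higher, unlike with GW9662. The tailbud program was higher and lens genes lower, as with GW9662. The sterol demethylase cyp51 rose 2.39-fold, from 7.32 ± 0.107 to 18.2 ± 1.37 FPKM (SD, n = 4), and the presomitic factor msgn1 3.21-fold, from 3.77 ± 0.461 to 13.2 ± 1.55 FPKM. The lens crystallin cryba1b was 2.35-fold lower, at 14.6 ± 2.51 against 34.7 ± 1.47 FPKM. Of 14433 genes tested, 2450 passed, 1341 higher and 1109 lower, and 132 of them changed at least 2-fold. Here too the balance depended on the scaling, with 1261 higher and 1391 lower under library totals, a scaling chosen after the data were seen. Of 30 lists, 13 passed, 7 higher and 6 lower, and the calls for cholesterol synthesis and tailbud genes also held with an estimated correlation.

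Sterol synthesis was the clearest change of a pathway. Of 19 cholesterol synthesis genes, 16 were higher and none lower, by either count (median 0.72, adjusted p = 1.14e-16, and 0.0129 with an estimated correlation). The squalene epoxidase sqlea rose 3.01-fold to 12.5 ± 1.48 FPKM, and hmgcs1 and fdps, early enzymes of the route, rose by a log2 of 0.75 ± 0.0581 (SE) and 0.72 ± 0.0529. Of 11 fatty acid synthesis genes, 3 were higher over all genes tested and 4 adjusted over the list alone, with none lower (median 0.25, adjusted p = 0.0038; adjusted p = 0.0686 with an estimated correlation, and 0.112 with a stricter filter on low genes). These were the desaturase fads2, 2.74-fold higher at 4.74 ± 0.551 FPKM, the elongase elovl2 at 1.02 and the lipogenic regulator mid1ip1b at 0.76. Of 22 PPARγ target and lipid storage genes, 9 were higher and none lower, by either count (median 0.20, adjusted p = 0.0152; adjusted p = 0.0699 with an estimated correlation). The secreted lipase inhibitor angptl4 rose 1.53-fold to 44.6 ± 1.24 FPKM (log2 0.61 ± 0.0492, SE), and pck1 and cebpb by a log2 of 0.59 and 0.37. Of 25 fatty acid oxidation genes, 6 were higher, among them the transporter cpt1ab at 0.67, and 3 lower over all genes tested, and 6 and 4 adjusted over the list alone, so the list did not pass (adjusted p = 0.279). The pparg gene was at 1.67 ± 0.111 FPKM, not different from DMSO (log2 0.14 ± 0.165, adjusted p = 0.644), and pparaa fell by 0.55 ± 0.127. The cofactor ppargc1b and the receptor rxrga (listed as CU855759.1) rose by 0.42 and 0.36, and rxrga was lower with GW9662, at -0.35.

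Tail mesoderm genes rose. Of 24 tailbud and segmentation genes, 18 were higher and 2 lower, by either count (median 0.52, adjusted p = 7.72e-10, and 0.0174 with an estimated correlation). The T-box gene tbx6 rose 2.88-fold, and its relative tbx6l, which is outside the list, 3.40-fold. The clock gene her1 rose 2.59-fold, and the retinoic acid hydroxylase cyp26a1, which clears the tail of this signal, rose 2.90-fold to 45.3 ± 2.86 FPKM. Only hes6 and her12 fell, by 0.49 and 0.39. Of 16 heart genes, 4 were higher and none lower (median 0.16, adjusted p = 0.014; adjusted p = 0.109 with an estimated correlation): gata6 rose by 0.66, hand2 by 0.39, tnnt2a by 0.35 and bmp4 by 0.22. Of 16 endothelial genes, 6 were higher and none lower, at the edge of the threshold (median 0.11, adjusted p = 0.0487; adjusted p = 0.12 with an estimated correlation). That call ended with a replicate block (0.0772) and under most other settings, including each other scaling tried (0.0504 to 0.0596) and each other filter (0.0532 and 0.0996). It also ended without DMSO replicate 3 (0.0728), DMSO replicate 4 (0.0681), rosiglitazone replicate 2 (0.0907) or rosiglitazone replicate 3 (0.0678). The vessel and blood regulators etv2, lmo2 and tal1, which act before vessels form, rose by 0.31, 0.37 and 0.51.

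Most stress genes did not pass. Over the 4 stress lists pooled (heat shock, oxidative stress, unfolded protein and p53), 21 of 85 genes were higher and 7 lower. The pool was higher as a set (median 0.0956, camera adjusted p = 0.00152), but was not tested with an estimated correlation. Of 18 heat shock genes, 8 were higher over all genes tested and 9 adjusted over the list alone, with none lower (median 0.24, adjusted p = 2.23e-05; adjusted p = 0.0877 with an estimated correlation), and hsp70.3 reached 11.5 ± 0.555 FPKM against 94.9 ± 10.9 with GW9662. The lists of oxidative stress (5 of 25 higher and 2 lower, 7 and 4 adjusted over the list alone; adjusted p = 0.11), unfolded protein and amino acid stress (5 of 23 higher, 3 lower; 0.633) and p53 targets (3 of 19 higher, 2 lower; 0.354) did not pass. Hypoxia genes, 7 of 17 higher and 1 lower, came close (0.059), and passed without DMSO replicate 1 (0.0404) or rosiglitazone replicate 1 (0.0386), with no filter on low genes (0.0264) and with a stricter one (0.0134). The oxidative stress list passed without rosiglitazone replicate 2 (0.0376), with no filter (0.0203) and with a robust prior (0.0335).

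Lens, muscle and pigment genes fell. Of 23 eye and lens genes, 14 were lower and none higher (median -0.68, adjusted p = 5.14e-10; adjusted p = 0.0576 with an estimated correlation), with crygmx at -2.21, mipb at -1.48 and cryba2a at -1.06. Of 36 skeletal muscle genes, 17 were lower and 6 higher over all genes tested, and 19 and 6 adjusted over the list alone (median -0.23, adjusted p = 1.89e-04; adjusted p = 0.509 with an estimated correlation). Rosiglitazone replicate 1 stood apart, with a mean log2 level of muscle genes of 6.58, inside the DMSO range of 6.57 to 6.61, against 6.30 to 6.33 in the other 3, and it also lay inside the DMSO range for the glycolysis, mitochondrially encoded and cell cycle lists. The muscle list also passed without it. The troponin tnnt3b fell by 0.76 and pvalb1 by 0.83, whereas the early regulators myf5, myog and myod1 rose by 0.73, 0.55 and 0.21, as did the fast myosin myhz2, by 0.33. Of 22 neural crest and pigment genes, 13 were lower and 5 higher (median -0.47, adjusted p = 4.36e-04; adjusted p = 0.12 with an estimated correlation), and the pigment enzymes tyrp1b, tyrp1a and gch2 fell by 1.23, 1.16 and 0.86. The 5 that rose were crestin at 0.62, foxd3 at 0.55, snai2 at 0.54, snai1b at 0.48 and tfap2c at 0.21, regulators or markers of early crest. Neural genes did not pass as a list, with 2 of 32 higher and 5 lower over all genes tested, and 3 and 7 adjusted over the list alone (adjusted p = 0.11). Glycolysis genes were lower for 9 of 24 and higher for 1, pgam1a at 0.23, over all genes tested, and for 10 and 2 adjusted over the list alone (median -0.16, adjusted p = 0.00257; adjusted p = 0.509 with an estimated correlation). Of 13 mitochondrially encoded genes, 5 were lower and 1, mt-co1 at 0.27 and without change under quantile normalization, higher, and 8 and 2 adjusted over the list alone (median -0.18, adjusted p = 0.0126; adjusted p = 0.616 with an estimated correlation). Cell cycle genes were lower for 4 of 30, namely bub1 at -0.25, ccnb1 at -0.20, kif11 at -0.18 and top2a at -0.15, and higher for 1, mcm3 at 0.16 (median -0.12, adjusted p = 0.0178; adjusted p = 0.632 with an estimated correlation). Adjusted over the list alone, 6 of the 30 were lower and 1 higher, and the call of the list ended without rosiglitazone replicate 2 (adjusted p = 0.0948).

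Among single genes, the bile salt pump abcb11a rose 4.99-fold, from 2.51 ± 0.106 to 14.6 ± 1.57 FPKM, the urate oxidase uox 4.72-fold to 21.6 ± 1.71 FPKM, and the conjugation gene ugt1ab by a log2 of 2.16 ± 0.122 (SE). The sulfotransferase sult6b1 and the transporter abcb5 rose by 1.78 and 1.71. These 5 genes were higher with GW9662 too, at 1.42 for abcb11a, 1.58 for uox, 2.06 for ugt1ab, 2.73 for sult6b1 and 1.61 for abcb5. The steroid enzyme cyp17a1 was 4.94-fold lower, at 1.37 ± 0.286 against 8.68 ± 0.660 FPKM, and the ammonium transporter rhbg was 2.91-fold lower. The fin fold genes and1, and2 and and3 fell by 1.56, 1.91 and 1.69. The apolipoprotein apoa4b.3 fell by 1.97 ± 0.374, but its sequence is near-identical to that of its neighbours. The means of the epidermis (-0.23), yolk lipoprotein (-0.12), hatching gland (-0.01) and notochord lists (0.02) had the opposite sign to their medians (0.02, 0.01, 0.05 and -0.02), and none of these lists passed.

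**Figure D3:**
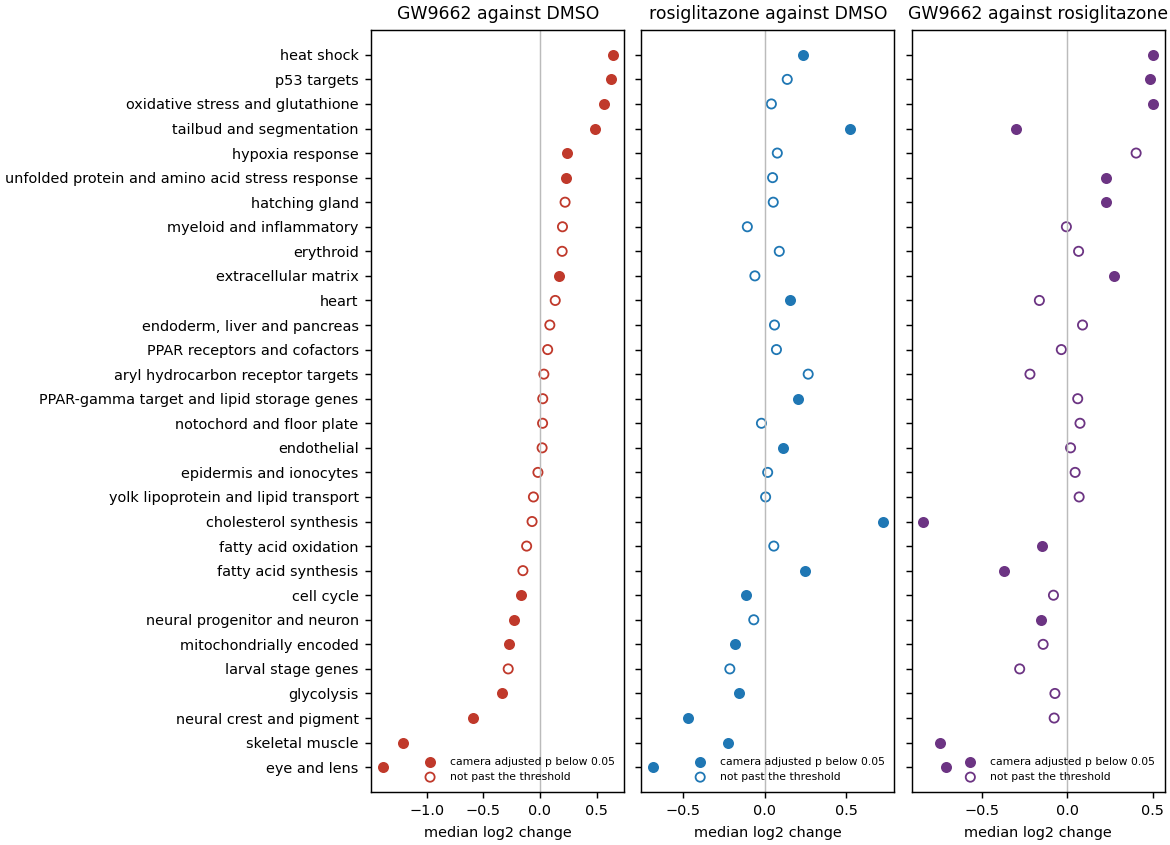
Median log2 change of each of the 30 gene lists in the 3 comparisons, a panel per comparison, with filled points where the camera adjusted p was below 0.05. The skeletal muscle list lies at -1.21 with GW9662 and -0.23 with rosiglitazone, and the cholesterol synthesis list at -0.07 and 0.72.

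Set directly against rosiglitazone, GW9662 embryos had more stress transcript and less muscle, lens and lipid synthesis transcript. The ddit3 gene was 5.06-fold higher, at 27.1 ± 2.61 against 4.94 ± 0.400 FPKM (SD, n = 4), and fads2 6.10-fold lower, at 0.376 ± 0.233 against 4.74 ± 0.551 FPKM. Of 14433 genes, 4398 passed, 2308 higher and 2090 lower with GW9662, and 394 of them differed at least 2-fold. Under quantile normalization 2151 were higher and 2449 lower. Of 30 lists, 13 passed, 6 higher and 7 lower, none of them with an estimated correlation.

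Lipid synthesis parted the compounds. Of 19 cholesterol synthesis genes, 15 were lower with GW9662 and 2 higher (median -0.84, adjusted p = 3.51e-08; adjusted p = 0.0576 with an estimated correlation). The sterol genes cyp51, sqlea and hmgcs1 differed by -1.14, -1.02 and -0.84, whereas fdps was alike (0.02 ± 0.0529 (SE), adjusted p = 0.834). Of 11 fatty acid synthesis genes, 6 were lower and 1, mid1ip1l at 0.49, higher (median -0.37, adjusted p = 0.0038; adjusted p = 0.0686 with an estimated correlation, and 0.187 with a stricter filter on low genes). The elongases elovl2 and elovl6 differed by -1.81 and -0.86. Of 25 fatty acid oxidation genes, 9 were lower and 2, slc25a20 at 0.29 and cpt1aa at 0.18, higher over all genes tested, and 11 and 2 adjusted over the list alone (median -0.15, adjusted p = 0.00901; adjusted p = 0.452 with an estimated correlation). The PPARγ target list was split, with 5 of 22 higher and 9 lower over all genes tested, and 7 and 10 adjusted over the list alone (median 0.06, mean 0.01, tested direction down, adjusted p = 0.633). Within it angptl4 was lower by a log2 difference of -0.41 and pck1 higher by 1.71, and pparg did not differ (-0.30 ± 0.165, adjusted p = 0.201).

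The 4 stress lists were higher with GW9662, whereas hypoxia genes did not pass (8 of 17 higher and 2 lower, adjusted p = 0.102). Of 18 heat shock genes, 12 were higher and 1, hspb11 at -0.52, lower (median 0.50, adjusted p = 3.86e-09; adjusted p = 0.0576 with an estimated correlation). Of 25 oxidative stress genes, 13 were higher and 2, nfe2l2b at -0.48 and srxn1 at -0.45, lower (median 0.50, adjusted p = 8.96e-06; adjusted p = 0.0686 with an estimated correlation). Of 23 unfolded protein and amino acid stress genes, 13 were higher over all genes tested and 14 adjusted over the list alone, with none lower (median 0.23, adjusted p = 3.19e-05; adjusted p = 0.0676 with an estimated correlation). Of 19 p53 targets, 12 were higher over all genes tested and 13 adjusted over the list alone, with none lower (median 0.48, adjusted p = 5.04e-05; adjusted p = 0.0576 with an estimated correlation). Of 26 extracellular matrix genes, 13 were higher and 1, col6a1 at -0.30, lower, and 14 and 1 adjusted over the list alone (median 0.27, adjusted p = 9.33e-05; adjusted p = 0.112 with an estimated correlation). Of 8 hatching gland genes, 5 were higher over all genes tested and 6 adjusted over the list alone, with none lower (median 0.23, adjusted p = 0.0251; adjusted p = 0.271 with an estimated correlation). These were ctslb at 0.60, he1.1 at 0.24, xbp1 at 0.23, tmem59 at 0.22 and klf17 at 0.20. The call of the hatching gland list ended without GW9662 replicate 4 (0.0593), with a robust prior (0.115) and with a stricter filter (0.0608).

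Of 36 skeletal muscle genes, 31 were lower with GW9662 and 1, myog at 0.47, higher over all genes tested, and 32 and 1 adjusted over the list alone (median -0.74, adjusted p = 6.24e-22; adjusted p = 0.0727 with an estimated correlation). In this list pvalb1 was 7.11-fold lower than with rosiglitazone and tnnt3b 3.54-fold lower. Of 23 eye and lens genes, 14 were lower and 2, rx3 and aldh1a3, each at 0.37, higher over all genes tested, and 16 and 4 adjusted over the list alone (median -0.71, adjusted p = 1.73e-07; adjusted p = 0.0686 with an estimated correlation). Of 32 neural genes, 14 were lower and 1, elavl4 at 0.23, higher (median -0.15, adjusted p = 9.57e-04; adjusted p = 0.271 with an estimated correlation). Of 24 tailbud and segmentation genes, 9 were lower and 2, aldh1a2 at 1.03 and tcf15 at 0.49, higher over all genes tested, and 11 and 2 adjusted over the list alone (median -0.30, adjusted p = 0.00747; adjusted p = 0.115 with an estimated correlation). In that list msgn1 and cyp26a1 differed by -0.80 and -1.31. The mitochondrially encoded and cell cycle lists did not pass. The first passed without GW9662 replicate 1 (0.0154), GW9662 replicate 4 (0.0461) or rosiglitazone replicate 2 (0.0198), and cell cycle genes without GW9662 replicate 4 (0.0351) or rosiglitazone replicate 2 (0.0376).

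Genes called with both the inhibitor and the agonist mostly moved the same way. Of 5975 genes called with either compound, 1671 were called with both, of which 852 were higher with both, 654 lower with both and 165 opposite. Independent calls would give 443.2 in the same direction and 438.8 opposite. Both comparisons share the DMSO libraries, which alone makes their changes correlate, so the comparison was repeated with 2 DMSO libraries for each compound. Then 836 to 904 genes went the same way and 70 to 95 opposite over the 6 ways to divide the controls. Across genes, which are not independent replicates, the changes correlated at a Pearson r of 0.52 and a Spearman rho of 0.47. Simulated groups without change gave 0.50 and 0.46, and divided controls 0.37 to 0.41 and 0.30 to 0.36. A correlation leaves out the size of the changes. Their covariance was 0.0685, against 0.0103 in the simulated groups and 0.0552 to 0.0589 with divided controls, so shared controls alone gave far less than was observed. The change was the larger with GW9662 for 1081 of the 1506 that shared a direction. The shared rises included ugt1ab, abcb5, tbx6 and fn1b, and the shared falls cryba1b, tyrp1b, and2 and cyp17a1.

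Of the 165 genes called in opposite directions, GW9662 lowered and rosiglitazone raised the desaturase fads2 (log2 -1.15 and 1.46), the elongase elovl2 (-0.80 and 1.02) and the copper carrier cp (-1.04 and 0.77). The ammonium transporter rhbg went the other way, at 0.39 and -1.54. The count of opposite calls was 102 without DMSO replicate 1, 106 without DMSO replicate 2, 119 without DMSO replicate 3 and 110 without DMSO replicate 4, and 120 to 170 without any 1 of the other libraries.

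**Figure D4:**
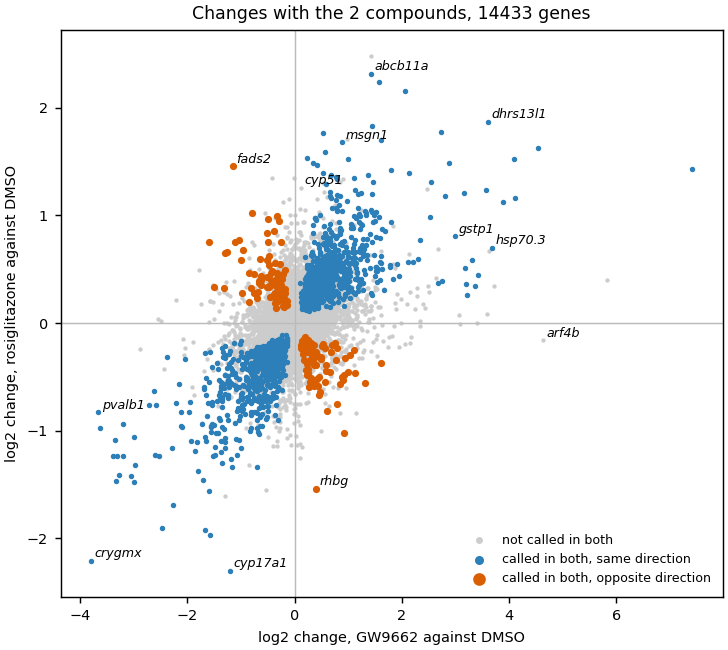
Log2 change of 14433 genes with GW9662 (horizontal) and rosiglitazone (vertical), each against DMSO, a point per gene. Blue marks the 1506 genes called with both compounds in the same direction and orange the 165 called in opposite directions.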

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

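The tests of library depth, of a single library, of the hours in the batch tag, of a delay differing only in length and of cholesterol genes under GW9662 were chosen only after the result was seen. The other tests of patterns were chosen before it.

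Of 531 sets of 4 libraries, 35 held a library that stood apart from the other 3, with a gap to the nearest that passed Dixon's test. Chance picks about 1 in 20 such groups, or 26.6. DMSO replicate 3 and rosiglitazone replicate 1 each stood apart 6 times, the others 4 times or fewer. Values of genes are FPKM, with the range of the other 3 libraries in parentheses.

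Rosiglitazone replicate 1 had higher myhz1.2 at 66.6 (54.9 to 55.9), eno3 at 95.3 (70.9 to 73.0), crygmxl2 at 2.82 (1.48 to 1.62) and igfbp1a at 10.34 (6.58 to 7.20). Its mean log2 level was 6.58 for muscle genes (6.30 to 6.33, with DMSO at 6.57 to 6.61) and 3.74 for endoderm and liver genes (3.50 to 3.54). DMSO replicate 3 had krtt1c19e at 81.8 (104 to 106), gch2 at 182 (192 to 194), ehhadh at 2.81 (3.52 to 3.65) and col6a1 at 8.03 (7.29 to 7.36). Its mean log2 level was 2.91 for cholesterol synthesis genes (2.95 in the others) and 3.36 for endoderm and liver genes (3.49 to 3.51). In DMSO replicate 4, msgn1 was 4.46 (3.47 to 3.61), dct 61.4 (55.3 to 56.3) and fga 75.0 (61.0 to 63.1), and in DMSO replicate 1 vcana was 11.4 (12.3 to 12.5).

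Among the GW9662 libraries, replicate 1 had high abcb11a at 9.36 (6.90 to 7.17), mmp9 at 8.17 (7.30 to 7.39), nppa at 0.805 (0.266 to 0.306) and sult6b1 at 338 (244 to 259). Replicate 4 had high cryba1b at 4.47 (2.93 to 3.06), crybb1l1 at 2.36 (1.47 to 1.58) and tyrp1a at 18.4 (15.4 to 15.7), and low fn1b at 17.0 (20.8 to 21.4). Replicate 3 had high apoa4b.3 at 9.67 (3.71 to 4.18), low eno3 at 37.2 (41.8 to 42.8) and low igfbp1b at 1.33 (1.95 to 2.06), and was the deepest library at 22.7 M fragments (16.2 to 16.9). Replicate 2 had a mean log2 level of 2.18 for fatty acid synthesis genes (2.297 to 2.32) and 3.09 for heart genes (3.02 in the others). In rosiglitazone replicate 3, the embryonic globin hbbe2 was 6.24 (13.0 to 13.8), pfkma 2.38 (2.59 to 2.61) and the mean log2 level of erythroid genes 4.43 (4.65 to 4.69). In rosiglitazone replicate 4, a2ml was 22.8 (29.7 to 30.8) and the mean log2 level of hatching gland genes 6.34 (6.18 to 6.19).

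Regrouping the 8 libraries of each comparison into 4 and 4 in all 35 ways tested the counts of calls. For genes, only the real split gave as many calls in each comparison, 1 of 35, the smallest share this test can reach. It gave 5196 calls against at most 1 in the others for GW9662, 2450 against 3 for rosiglitazone and 4398 against 1 between the compounds. That makes a random grouping unlikely, but other splits count the group difference as spread, so their few calls were fixed in advance. Nor can the splits part the compounds from a batch that follows the groups. For lists the real split also stood alone for rosiglitazone, with 13 against 11 in the next. For the number of lists with GW9662, 2 splits reached 14 and the highest other split gave 14. Between the compounds, 7 splits reached 13 and the highest other gave 15. Splits with 3 libraries of a group on a side keep part of the group difference, however. In all 3 comparisons the list counts can therefore neither exclude chance nor speak for it. Splits with 2 libraries of each group on each side, which balance the groups, still called up to 3, 7 and 7 lists.

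Stress genes were higher in the GW9662 libraries. Of 85 members of the 4 stress lists, 54 were higher and 6 lower with GW9662, against 21 and 7 with rosiglitazone. Depth is argued against by thinning every library to 12.77 M fragments, after which the median change with GW9662 was 0.371, against 0.383 before. A single library is argued against by leaving each out in turn, which left at least 53 members higher. A response to an electrophile, which would raise glutathione and chaperone genes through modified proteins, was predicted to raise proteasome subunits too. Of 33, none was higher and 14 were lower, with a median of -0.177 (adjusted p = 0.00538, lower in 4 of 4 libraries, but p = 0.323 with an estimated correlation). Their median was -0.153 with rosiglitazone, and between the compounds it was -0.0225, with 1 higher and 3 lower. The prediction failed. Under an equal fall with both compounds, an added rise with GW9662 would have left these genes higher with GW9662 than with rosiglitazone. They were not, which argues against a response that raises proteasome subunits. An electrophile response without such a rise stays open. So does a toxic effect of the dose apart from the receptor, for which the design has no group.

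Tailbud genes were higher and lens and muscle genes lower with both compounds. Embryos collected at the ages in the batch tag would make the rosiglitazone libraries the oldest, but their tailbud genes rose, by a median of 0.519. A younger stage at collection predicted lower synapse and transmitter genes, a late list not looked at before as a whole. These had medians of -0.394 with GW9662 and -0.146 with rosiglitazone, with 14 and 4 of 22 lower. Slower development in both groups would give this fall, but the fall does not single it out. Of 32 neural genes, 19 had already been seen lower and 1 higher with GW9662. As the whole of the pattern, 1 delay of different lengths is argued against. GW9662 had the lower muscle genes and yet the lower tailbud genes, by a median of -0.299, with 9 of 24 lower and 2 higher (camera adjusted p = 0.00747, but 0.115 with an estimated correlation). A direct effect on muscle or lens, and embryos staged or collected differently, stay open.

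Cholesterol synthesis genes were higher with rosiglitazone. Depth is argued against by a median of 0.702 after thinning, against 0.723. A younger stage predicted that GW9662, with which tailbud genes rose, would raise cholesterol genes too, but their median there was -0.07. With GW9662, 5 of 19 were higher and 3 lower, and set directly against rosiglitazone 15 were lower and 2 higher. That argues against a younger stage shared by both compounds as the whole cause. Whether GW9662 itself lowered these genes was not tested. A shortage of sterols would lower LXR targets, but of 5 measured none was higher and 1 lower, with a median of -0.034, too few and too small a change to decide. A shortage of sterols stays open, as do a part played by a younger stage and an effect on the enzymes' regulators.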

How the results depend on the processing

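The tests with voom and with library totals were chosen only after the data were seen. All 3 gene counts held within 1.5 times under pseudocounts, filters, scalings and variance models: 3850 to 5938 for GW9662, 2032 to 2844 for rosiglitazone and 3293 to 4714 between the compounds. Asking also for a log2 change of at least 1 left 568, 132 and 394, by construction. Leaving out each library gave 4502 to 5583, 1837 to 2494 and 3736 to 4359 genes, of which at least 4413, 1784 and 3612 were the same genes, and 14 to 15, 12 to 14 and 13 to 15 lists. A replicate block gave 5329, 2433 and 4454 genes and 14, 12 and 14 lists. Voom gave 5423, 2678 and 4669 genes, and library totals 5407, 2652 and 4516. Which direction had more calls turned with these: 2447 higher and 2976 lower, 1236 and 1442, and 2287 and 2382 with voom, and 2431 and 2976, 1261 and 1391, and 2189 and 2327 with library totals. It also turned under quantile normalization with GW9662 (2529 and 3001) and between the compounds (2151 and 2449), and there under median-ratio scaling (2231 and 2239). With an estimated correlation camera called 0, 2 and 0 lists, and fry, which compares a list with no other genes, called 25 for GW9662. The wider spread allowed for correlated genes is the construction of the former. The correlation of the compounds was 0.5022 without a filter and 0.5491 with a stricter one, where the cause was not tested, and 0.4971 to 0.5367 with each library left out. With divided controls it was 0.4123, 0.3834, 0.3794, 0.3741, 0.3912 and 0.4023, same-direction calls were 839, 836, 866, 876, 904 and 839, and opposite calls 85, 70, 81, 79, 95 and 75, with fewer controls per comparison. Leaving out each library gave 1175 to 1595 same-direction and 102 to 170 opposite calls. Of 2421 values of lists under the alternatives, 2312 kept their side of the threshold, 62 lost the call and 47 gained it. Of 10659 values of named genes, 10344 kept their side, 248 lost the call and 67 gained it. No list or gene called in the main test or in the alternative turned its direction. A turn between values not called in either was not counted. Depth limited lens genes with GW9662 and arf4b without it, which rested on few fragments.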

Other observations

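Some families of genes with a shared symbol stem held more calls in 1 direction than other genes did. The hoxb genes, which are in none of the lists and set position along the trunk, parted the compounds: of 13 measured, 11 were higher with rosiglitazone (Fisher's exact test, one-sided, adjusted p = 1.23e-07), whereas with GW9662 8 were lower and 2 higher (adjusted p = 0.0313). With GW9662 hoxb4a, hoxb5a and hoxb8a fell by a log2 of 0.84, 0.98 and 0.75, and with rosiglitazone they rose by 0.19, 0.28 and 0.28. The 2 that were higher with GW9662, hoxb7a and hoxb10a at 0.85 and 0.46, were also higher with rosiglitazone, at 0.83 and 0.33. The 2 not called with rosiglitazone were hoxb8b and hoxb13a, at 0.38 and -0.34. Of 9 retinol dehydrogenase genes (rdh), 7 were higher and 1 lower with GW9662 (exact adjusted p = 0.0191), among them rdh10a and rdh10b at 0.80 and 0.99.

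Of 244 solute carriers (slc), 92 were higher and 45 lower with GW9662 (exact adjusted p = 2.65e-09 for more higher calls than among all genes), and 45 higher and 27 lower with rosiglitazone (exact adjusted p = 0.00129). Of 38 cytochrome genes (cyp), of which cyp51, cyp26a1, cyp1a and cyp1c1 are also in the lists, 18 were higher and 8 lower with GW9662 (exact adjusted p = 0.00649), and 13 higher and 4 lower with rosiglitazone (exact adjusted p = 0.00337). The vitamin D hydroxylase cyp24a1 rose by 2.81 and 1.18, and cyp2aa8 by 1.14 and 0.78, whereas the activating enzyme cyp27b1 fell by 0.70 and 1.34. Of 10 alpha tubulins, near-identical copies among them, 8 were lower with GW9662 (exact adjusted p = 0.00337), and 5 were lower and 1 higher with rosiglitazone (exact adjusted p = 0.0335), with tuba8l4 going from 1458 ± 42.4 to 972 ± 42.3 FPKM with GW9662 (SD, n = 4).

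These tests and the members named were chosen after seeing the data: symbols sharing a stem formed 220 families, and 19 of 1320 tests passed. Members of a family are not independent, so the p-values are too small by an unknown amount. Under median-ratio scaling, quantile normalization and library totals no called member of the 19 turned its sign, and the direction with more calls was the same in each. Library totals left 80 solute carriers higher with GW9662 and 41 higher against 36 lower with rosiglitazone.

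A short ribosomal RNA annotated as the 5.8S type (RF00002) averaged 403.2 fragments in the GW9662 libraries (297 to 520), against 41.75 in DMSO (33 to 57) and 47.25 in rosiglitazone (39 to 53). The counts are a trace of each library and were not tested. Another ribosomal gene, CT583728.7, had 195 fragments in GW9662 replicate 4 and none in the other libraries.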
